A study of Mus musculus with 4 samples.

How the data were processed

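Nuclear RNA of mouse kidney cortex was measured by droplet-based single-nucleus RNA sequencing on the 10X Chromium system, which tags each RNA molecule with a unique molecular identifier (UMI) and each nucleus with a barcode. Per the labels' protocols, kidneys were perfused with a buffered salt solution and kept in an RNA-preserving solution at low temperature, and nuclei were released from a small piece of cortex with a detergent buffer, filtered and washed. The labels name 4 genotypes on C57BL/6J, with 1 library each: Klf4 flox/flox (called the control), Klf4 flox/flox with Klf4 deleted in endothelial cells (called Klf4 dEC), Nos3 null, and both together (called Klf4 dEC Nos3 null). Klf4 is a zinc-finger transcription factor and Nos3 is endothelial nitric oxide synthase. Whether a library holds 1 mouse or several is not given in the sources used here.

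Per the submitters' processing notes, Cell Ranger, Seurat and the mm10 mouse genome build were used, with no versions given. The deposited table holds a normalized signal for 21046 genes in 92 columns, which are 23 numbered clusters in each of the 4 libraries. Every column sums to 10000, so each value is a mean over the nuclei of that cluster and library of UMIs per 10000 UMIs. The clustering is the authors', per the column names; how it was done, how doublets were treated and which nuclei were left out are not given in the sources used here. All 92 columns were matched to libraries through the library titles, and 0 other columns of values were left over.

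Because the table holds averages, nuclei numbers and depth were recovered by arithmetic and are inferred values. A gene with 1 UMI in 1 nucleus has a value equal to 10000 divided by the nucleus's UMI total and by the number of nuclei, so the reciprocals of the lowest values share that number as a divisor. The number taken was the largest that divided at least 85% of the reciprocals, within a relative tolerance of 3e-14. The lowest share of reciprocals divided by the number taken was 92.3% over the columns, and the highest share divided by its double was 64.1%. In simulated columns the nuclei number was recovered exactly in 16 of 16. The effective UMI total was off by at most 19.1% (10.7% for endothelial columns). The counting intervals covered the true ratio for 94.1% to 95.1% of unchanged genes. All simulated nuclei of a column shared the same expression profile, which the intervals assume, so coverage with varied nuclei was not tested. The level equal to 3 counts in endothelial nuclei was 0.0656, 0.0660, 0.0667 and 0.0794 per 10000 in the control, Klf4 dEC, Nos3 null and Klf4 dEC Nos3 null.

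Clusters were named from marker genes fixed before the data were examined, as were the gene lists, the size limit, the filter, the rule for named genes and the alternative settings. A cluster was called, for example, endothelial cell-like where the mean scaled level of that type's markers was at least 1 and led the next type by 0.5, at least 3 markers were detected, and no other type had more markers among its 10 leading genes. It otherwise stayed unnamed. These naming limits were set after the table was seen. This gave proximal tubule-like (clusters 0, 1, 3, 5, 6 and 12), thick ascending limb-like (2, 4 and 19), principal cell-like (8), distal convoluted tubule-like (9), endothelial cell-like (10), connecting tubule-like (11), intercalated cell-like (14 and 16), podocyte-like (15), thin limb-like (18), urothelium-like (20), macrophage-like (21) and cycling cell-like (22) classes, with clusters 7, 13 and 17 unnamed. The level of a class is the mean over its clusters weighted by nuclei. Cluster 2 holds the most thick ascending limb-like nuclei in 3 libraries and cluster 4 in the library labelled Nos3 null, with 459 nuclei in cluster 2 and 524 in cluster 4.

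For each of 5 comparisons between libraries, each gene got a log2 ratio of (value + 0.1) to (value + 0.1) per 10000, which understates the ratio of low genes. Genes entered where the higher of the 2 libraries reached 0.5 per 10000, and genes at a log2 ratio of at least 1 or at most -1 were counted. With 1 library per genotype there is no test, no p-value and no standard error. The ranges in brackets are 95% counting intervals: exact Poisson intervals for levels, and for ratios exact binomial (Clopper-Pearson) intervals of the ratio without the pseudocount, on the effective UMIs. They cover counting error only and leave out differences between nuclei of a cluster, mice, dissections and preparations. A run of 100 simulations with equal true levels gave the number of genes that counting error alone takes past the limit. In simulated comparisons, 34.3% to 41.8% of genes with a 2-fold change and 92.4% to 97.0% of genes with a 4-fold change passed the limit.

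Genes named in the text were taken from ranks fixed beforehand: per comparison, the 10 highest and 10 lowest log2 ratios in endothelial cell-like nuclei, the 3 highest and 3 lowest in each other class, and the 5 highest and 5 lowest for the interaction. Of the ranks in other classes only some genes in some classes and comparisons are printed, chosen after their values were seen. Predicted gene models, mitochondrially encoded genes and sex genes are left out of these ranks but not of counts. Members of 24 gene lists are named as well. Of the genes these rules take, 3 are not reported here. Among them are the KLF family, anticoagulant, procoagulant, leukocyte adhesion, nitric oxide and cGMP, antioxidant, interferon, VEGF and angiopoietin, junction, matrix, integrin, slit diaphragm, fatty acid oxidation, hypoxia, circadian clock, immediate early, unfolded protein response and mitochondrially encoded genes. Markers of 18 cell types serve as lists of RNA from other cells. The median log2 ratio of a list with at least 5 genes past the filter is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Complement components, complement regulators, tubular injury genes and erythrocyte genes had under 5 such genes in endothelial cell-like nuclei and have no median there, and 10 listed genes are not in the table. The sex genes were read as a label check: all 4 libraries had Uty between 2.83 and 2.91 and Xist at or below 0.00511 per 10000. With the same pattern in all 4, the check could not detect labels exchanged between them.

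Alternatives were pseudocounts of 0.01 and 0.5, no filter and a filter of 2, all per 10000, a size limit of 0.6, and rescaling each endothelial library by its median ratio to the geometric mean of the 4. A further pair was added after the data were seen: subtracting the median log2 ratio of the other clusters among the first 20, and leaving out genes whose endothelial level lies under 10% of their highest level in another cluster. The plan for cell class shares required single nuclei, so no share is given as a planned result, and shares from the inferred nuclei numbers stand among the closing observations. Gene positions are from the GENCODE mouse annotation of the GRCm38 (mm10) build, where 20715 of the 21046 symbols were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.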

Results

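Single-nucleus expression was profiled in kidney cortex from 4 mouse genotypes, 1 library each, which cross endothelial deletion of Klf4 with loss of Nos3. The series title gives the question as the effect of lowering endothelial Klf4 on a wild-type and on a Nos3-deficient background. The inferred numbers of nuclei were 6766 in the control, 6883 in Klf4 dEC, 7004 in Nos3 null and 5491 in Klf4 dEC Nos3 null, 26144 in all. Endothelial cell-like nuclei numbered 270, 284, 327 and 186 in that order, with median totals of 1838, 1647, 1332 and 2275 UMIs. All levels are mean UMIs per 10000 UMIs. No genotype has a replicate library, so every difference below is a difference between individual libraries, and no p-value or standard error is given.

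The targeted genes were read first, and neither was lower where its label says it was deleted. Klf4, on chromosome 4 from 55527143 to 55532466 on the minus strand, stood in endothelial cell-like nuclei at 0.621 (0.407 to 0.885) in the control, 0.779 (0.536 to 1.07) in the library labelled Klf4 dEC, 0.445 (0.272 to 0.687) in the library labelled Nos3 null and 0.824 (0.557 to 1.16) in the library labelled Klf4 dEC Nos3 null. Its log2 ratio was 0.29 (-0.43 to 1.10) for Klf4 dEC over control and 0.76 (0.03 to 1.77) for Klf4 dEC Nos3 null over Nos3 null. Nos3, on chromosome 5 from 24364810 to 24384474 on the plus strand, stood at 1.26 (0.963 to 1.64), 0.930 (0.666 to 1.25), 1.52 (1.17 to 1.92) and 2.07 (1.63 to 2.58) in the same order. Its log2 ratio was 0.25 (-0.27 to 0.78) for Nos3 null over control and 1.07 (0.60 to 1.74) for Klf4 dEC Nos3 null over Klf4 dEC. In unnamed cluster 13, Klf4 stood at 0.965 (0.737 to 1.23) in the library labelled Klf4 dEC, above its endothelial level, against 0.213 in the control. The labels do not say which part of either gene was removed, and 3' tags outside the removed part check nothing. Because the levels do not show the labelled deletions, each library is called by its label throughout, and every direction below is one between labelled libraries.

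**Figure D1:**
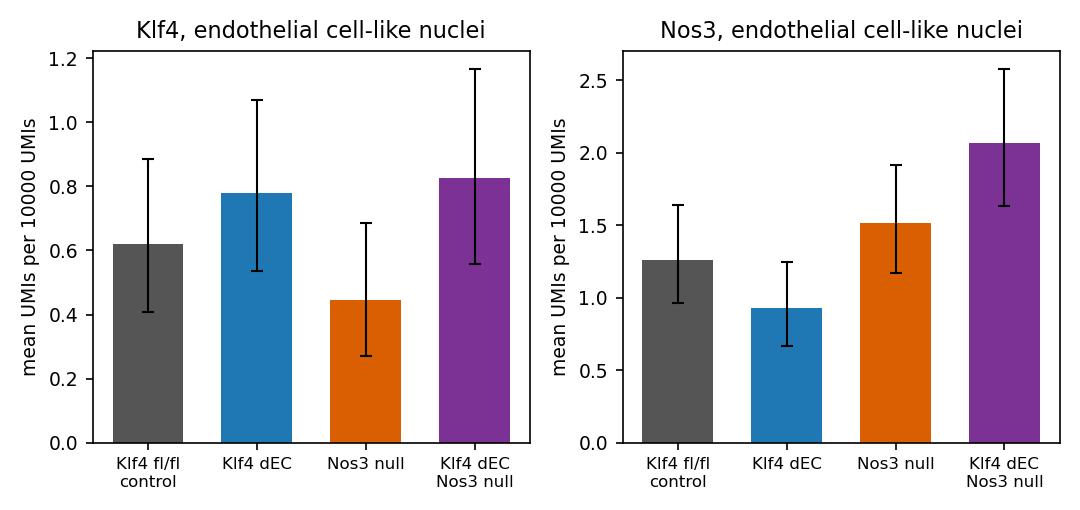
Bars give Klf4 (left) and Nos3 (right) in endothelial cell-like nuclei of each library, in mean UMIs per 10000 UMIs, and whiskers give 95% counting intervals. Klf4 was 0.621 in the control and 0.824 in the library labelled Klf4 dEC Nos3 null, and Nos3 was 1.26 and 2.07 in these libraries.

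The library labelled Nos3 null differed from the other libraries in transcripts from outside the nucleus and from other cell types, which were compared in the first 20 of the 23 clusters. It had the lowest depth, with a nuclei-weighted median of 2534 UMIs against 4840 in the control, 4215 in Klf4 dEC and 5456 in Klf4 dEC Nos3 null. Mitochondrially encoded transcripts, which come from outside the nucleus, were lower in it than in the control in 20 of 20 clusters, with a median list log2 ratio of -1.21 (range over clusters -1.57 to -0.79). Proximal tubule markers such as Lrp2 and Cubn, endocytic receptors of that segment, were higher in 14 of 14 clusters not named proximal tubule-like, with a median of 1.38 (range 0.05 to 1.78). By genes past the limit it was not the furthest from the control in unnamed cluster 13, with 82 higher and 227 lower against 146 and 206 in Klf4 dEC Nos3 null. In the library labelled Klf4 dEC over control the same 14 clusters gave a median of 0.07 for the proximal tubule markers, and in Klf4 dEC Nos3 null over control -0.33.

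**Figure D2:**
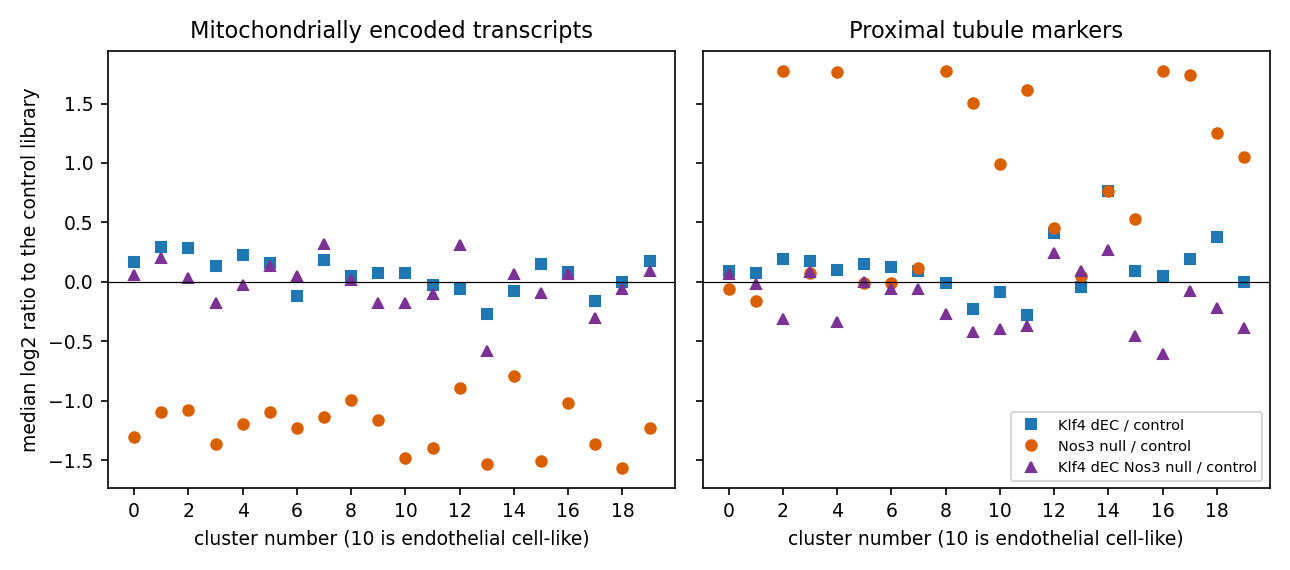
Points give, for the first 20 clusters (x axis, cluster number), the median log2 ratio to the control library of mitochondrially encoded transcripts (left) and of proximal tubule markers (right), with 1 symbol per library. The library labelled Nos3 null lies below 0 in 20 of 20 clusters on the left, with a median of -1.21.

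The first comparison asks what differs between libraries labelled with and without deletion of endothelial Klf4, both with Nos3 intact per the labels. In endothelial cell-like nuclei, 64 genes were higher and 84 lower by the size limit in the library labelled Klf4 dEC than in the control, of 4371 genes. Among the highest were Gzmk, a granzyme protease of lymphocytes, at 0.830 against 0.174, a log2 ratio of 1.77 (1.13 to 3.57), and Npr3, the clearance receptor for natriuretic peptides on chromosome 15 from 11839896 to 11907287, at 2.15 against 0.714, a log2 ratio of 1.47 (1.00 to 2.19). Lmna, which encodes nuclear lamins, was at 1.47 (0.88 to 2.81), and Hif1a, the hypoxia-inducible transcription factor subunit, at 1.30 (0.65 to 2.37). Also among the 10 highest were Ppme1, Rapgef4os1, Pex3, and the respiratory chain genes Atp5e and Cox7c, between 1.31 and 1.44. Cox7c, Atp5e and Lmna were higher outside endothelial nuclei too, with median log2 ratios over the other clusters of 0.93, 0.60 and 0.46. For the other genes named here that median was 0.20 or lower.

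Lower in the library labelled Klf4 dEC were Gpc6, a cell-surface heparan sulphate proteoglycan, at 0.249 against 1.96 (log2 ratio -2.56, -4.08 to -2.12), and Loxl2, a lysyl oxidase-like enzyme that cross-links collagen, on chromosome 14 from 69609068 to 69695834, at 0.0658 against 0.876 (-2.56, -6.07 to -2.08). Reln, a secreted extracellular matrix glycoprotein, was at 0.143 against 1.23 (-2.46, -4.37 to -1.85), and Adh1, an alcohol and retinol dehydrogenase, at -1.92 (-4.72 to -1.23). The other 6 of the 10 lowest were Dgkb, Pcdh9, Hnf4aos, Cys1, Dmd and Pcsk6, between -2.25 and -1.62. Gpc6, Reln and Dgkb were below the control in the library labelled Nos3 null too, at 0.451, 0.195 and 0.148. Hnf4aos and Cys1 were not below the control there. Gpc6, Dgkb, Pcdh9 and Dmd had their highest level outside endothelial nuclei in unnamed cluster 13, at 13.4, 5.00, 4.09 and 6.66. Hnf4aos reached 13.4 in proximal tubule-like cluster 0, and Pcsk6 reached 7.37 in thick ascending limb-like cluster 2. Loxl2 was lower in 20 of 20 clusters, the endothelial one included, and Npr3 reached 3.59 in the podocyte-like cluster.

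Among the lists in this comparison, 8 of 11 antioxidant genes lay above 0, with a median of 0.34 at percentile 99.6. They include the glutathione peroxidase Gpx1 at 0.79, the peroxiredoxin Prdx1 at 0.71 and the NADPH oxidase subunit Cyba at 0.62, while the glutathione synthesis gene Gclm was at -0.52. Of the KLF family, 5 of 7 measured genes lay above 0 (median 0.33, percentile 98.4), with Klf6 at 0.63, Klf2, a flow-responsive endothelial factor, at 0.38 and Klf9 at 0.36. Of the procoagulant genes 1 of 5 lay above 0 (median -0.41, percentile 4.72), with von Willebrand factor (Vwf) at -0.46 and factor VIII (F8) at -0.41. VEGF and angiopoietin genes were split, 7 of 16 above 0 (median -0.21, percentile 4.59). The apelin receptor Aplnr was at 0.167 against 0.653, Vegfa had a log2 ratio of -0.97 and Ehd3, a glomerular endothelial gene, of -0.89, against Nrp1, a VEGF co-receptor, at 0.80.

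Thrombomodulin (Thbd), a cofactor for protein C activation on chromosome 2 from 148404466 to 148408188, was at 0.190 in the library labelled Klf4 dEC against 0.673 in the control, a log2 ratio of -1.42. The whole anticoagulant list had 3 of 10 genes above 0 (median -0.07, percentile 31.9). Interferon genes had a median of 0.19 (percentile 93.3), with the GTPase Iigp1 at 1.04. Slit diaphragm and podocyte cytoskeleton genes, which endothelial nuclei share in part, had 1 of 10 above 0 (median -0.24, percentile 2.69), and thick ascending limb markers, RNA of another cell type, 1 of 5 (median -0.48, percentile 0.595). The other medians were 0.17 for leukocyte adhesion genes (percentile 83.2), 0.09 for nitric oxide and cGMP genes (78.1), 0.01 for junction genes (50.7), 0.02 for matrix genes (58.1) and -0.09 for integrins (28.3). They were -0.12 for fatty acid oxidation (34.9), 0.09 for hypoxia genes (75.7), -0.15 for clock genes (25.6), -0.15 for the unfolded protein response (23.8) and 0.08 for mitochondrially encoded transcripts (64.8).

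Counting error alone took a mean of 19.9 genes past the limit in simulations, against 148 in this comparison. Klf4 itself was not lower in the library labelled Klf4 dEC, and with a pseudocount 5 times as large 16 genes passed the limit.

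**Figure D3:**
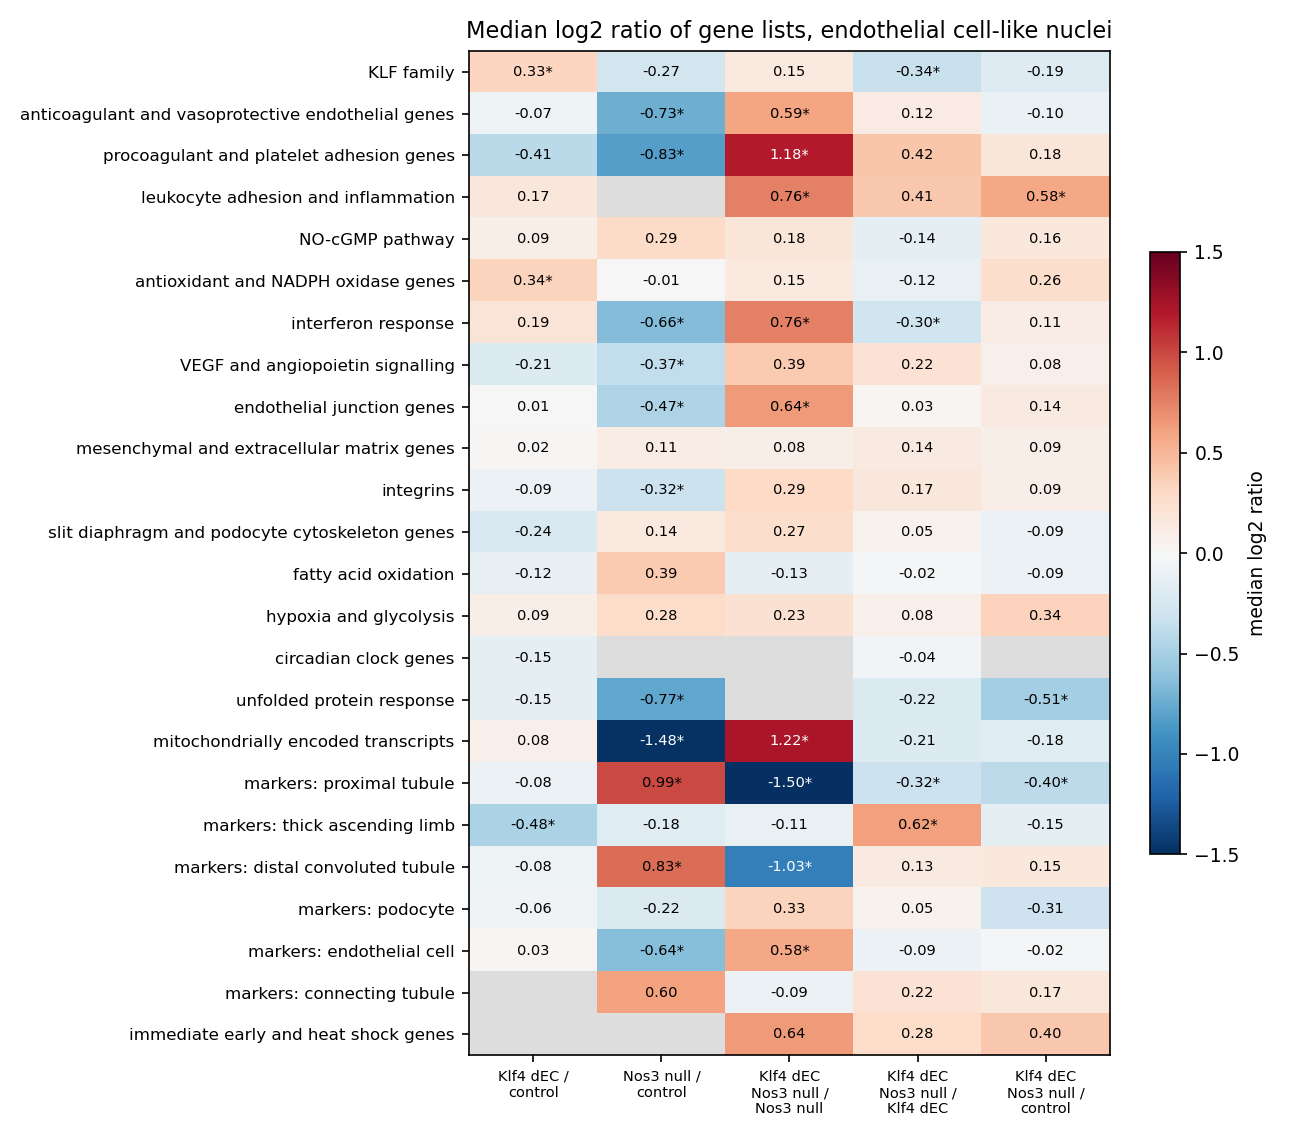
Each cell gives the median log2 ratio of a gene list (y axis) in endothelial cell-like nuclei for 1 of 5 comparisons (x axis), with an asterisk where the list lies in the outer 2.5% at either end of 10000 matched random lists. Grey cells had under 5 genes, and the mitochondrially encoded list runs from -1.48 for Nos3 null over control to 1.22 for Klf4 dEC Nos3 null over Nos3 null.

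The comparison of Nos3 null with control asks what differs with loss of Nos3, as labelled, and Klf4 intact. In endothelial cell-like nuclei 332 genes were higher and 286 lower in the library labelled Nos3 null, of 4478. Zbtb16, a transcription factor induced by glucocorticoids, on chromosome 9 from 48654297 to 48836222, was at 1.67 against 14.5 (log2 ratio -3.04, -3.48 to -2.77). Thbd was at 0.0437 against 0.673 (-2.43, -7.04 to -1.96), Id3, a target of BMP signalling, at 0.0579 against 0.935 (-2.71, -6.15 to -2.17), and H2-D1, an MHC class I heavy chain, at 0.571 against 3.43 (-2.39, -3.23 to -1.97). The others of the 10 lowest were Kap, an abundant proximal tubule transcript, the ribosomal gene Rpl7, Tmem176a, the neonatal Fc receptor Fcgrt, ferritin heavy chain Fth1 and the ubiquitin gene Ubb, between -2.67 and -2.25.

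Higher in the library labelled Nos3 null were Rims2, a synaptic vesicle scaffold, at 2.87 (2.41 to 4.88), Epb41l3 at 2.78 (2.30 to 4.35) and Slc12a3, the thiazide-sensitive sodium chloride cotransporter of the distal convoluted tubule, at 9.84 against 1.61 (2.54, 2.24 to 2.98). Unc13c, Igsf11, Akr1c21, Gabrb1, Stxbp5l and Gas2 were also among the 10 highest, between 2.27 and 2.58. Slc12a3 reached 192 in cluster 9, the distal convoluted tubule-like one, and its median log2 ratio over the other clusters was 1.98. Of these 9 genes, 8 had their top level outside endothelial nuclei in a tubule-like cluster, and Gabrb1 had it in the podocyte-like cluster.

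Endothelial markers lay below 0 in 14 of 14 in this library (median -0.64, percentile 0.03), among them the VEGF receptor Kdr at -1.09 and Adgrl4 at -1.22, while 12 of 14 proximal tubule markers lay above 0 (median 0.99, percentile 100) and 7 of 7 distal convoluted tubule markers (median 0.83, percentile 99.5). Beside these, 9 of 10 anticoagulant genes lay below 0 (median -0.73, percentile 0.11), with Plat, tissue plasminogen activator, at -1.31 and Klf2 at -1.03, and Nos3 alone above 0 at 0.25. Procoagulant genes were below 0 in 5 of 5 (median -0.83, percentile 0.74), with F8 at -1.31 and Vwf at -0.94. Junction genes had a median of -0.47 (percentile 0.60), with β-catenin (Ctnnb1) at -1.23, and interferon genes -0.66 (percentile 0.675), with Xaf1 at -1.33. VEGF and angiopoietin genes had a median of -0.37 (percentile 1.73), with Plvap, a fenestral diaphragm protein, at -1.40, integrins -0.32 (percentile 1.85, but 3.92 with 5 expression bins) and the unfolded protein response -0.77 (percentile 1.92), with Xbp1 at -1.65. Mitochondrially encoded transcripts were below 0 in 11 of 11 (median -1.48, percentile 0).

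Across genes, the endothelial log2 ratios correlated with the median of the other clusters at a Pearson r of 0.57. Of the 618 genes past the limit, 290 went in the same direction in that median, counted with a cut-off lower than the limit. After that median was subtracted, a step chosen after the data were seen, 387 genes passed, 126 higher and 261 lower. Without that step, a pseudocount 5 times as large gave 229 genes in place of 618. Genes are not independent replicates, and no p-value is given.

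With both libraries labelled as lacking Nos3, the comparison of Klf4 dEC Nos3 null with Nos3 null asks what differs with the label of endothelial Klf4 deletion. Of 4720 genes in endothelial cell-like nuclei, 433 were higher and 413 lower. Higher were Ubb at 2.27 against 0.178 (log2 ratio 3.09, 2.63 to 4.93), Adgrg6, an adhesion G protein-coupled receptor, at 1.58 against 0.108 (3.01, 2.53 to 5.51), Fth1 at 10.1 against 1.21 (2.97, 2.66 to 3.52), H2-D1 at 2.70 (2.28 to 3.54) and Ramp2, the co-receptor for adrenomedullin in endothelium, at 2.60 (2.13 to 5.14). Rpl29, Chchd10, Kap, Ndufb11 and Rpl27-ps3, mostly ribosomal or mitochondrial genes, completed the 10, between 2.60 and 2.90. Lower were Epb41l3 at 0.0974 against 2.07 (-3.46, -6.19 to -2.88), Pdzrn3, Ctnna2, Igsf11, Hnf4g, Ror1, Rims2, Slc22a23, and Fut9, a fucosyltransferase at 4.40 against 35.3 (-2.98, -3.25 to -2.78). Ror1 had its top level outside endothelial nuclei in thin limb-like cluster 18. The other lower genes had it in proximal tubule-like clusters, with Fut9 at 64.5 in cluster 5. Their median log2 ratios over the other clusters were also below 0, between -1.95 and -0.96.

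Procoagulant genes lay above 0 in 5 of 5 (median 1.18, percentile 100), with Vwf, on chromosome 6 from 125546774 to 125686679, at 1.45 against 0.275 (log2 ratio 2.04) and F8 at 1.32. Junction genes were above 0 in 10 of 10 (median 0.64, percentile 99.9), with Jam2 at 1.29, anticoagulant genes in 8 of 9 (median 0.59, percentile 99.2), with Klf2 at 1.61, and interferon genes in 8 of 9 (median 0.76, percentile 98.7), with Iigp1 at 1.51. Leukocyte adhesion genes were above 0 in 8 of 8 (median 0.76, percentile 98.1), with Icam2 at 1.54 and Vcam1 at 0.85. Moving with them, endothelial markers had a median of 0.58 (15 of 15 above 0), mitochondrially encoded transcripts 1.22, proximal tubule markers were below 0 in 12 of 14 and distal convoluted tubule markers had a median of -1.03. The library labelled Nos3 null is the denominator here and the numerator above, so a gene apart in that library alone is far from 0 in both comparisons, with opposite signs. Klf4 was not lower in the library labelled Klf4 dEC Nos3 null, at 0.76. With the larger pseudocount 366 genes passed the limit, and under median-ratio rescaling, which shifts this comparison by -0.17, the split became 292 higher and 513 lower. The ratios correlated with the median of the other clusters at a Pearson r of 0.60. After that median was subtracted, a step chosen after the data were seen, 333 genes were higher and 236 lower.

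With both libraries labelled as deleted for endothelial Klf4, a deletion their Klf4 levels do not show, the comparison of Klf4 dEC Nos3 null with Klf4 dEC asks what differs with the label of Nos3 loss. In endothelial cell-like nuclei 147 genes were higher and 76 lower, of 4526. Higher were Adamtsl1, a secreted ADAMTS-like matrix protein, at 2.31 against 0.419 (log2 ratio 2.21, 1.73 to 3.26), and the heparan sulphate sulphotransferases Hs6st3, at 2.01 against 0.364 (2.19, 1.66 to 3.28), and Hs3st4, at 0.539 against 0.0630, from 20 and 3 UMIs. BC003331, the lipopolysaccharide-binding protein gene Lbp, the creatine kinase gene Ckb, Negr1, Pdlim1, Pcdh9 and the haem exporter Flvcr1 completed the 10, between 1.63 and 1.88. Lower were the ephrin receptor Epha6 at 0.0504 against 0.623 (-2.27, -6.66 to -1.55), the cadherin Cdh18 at -2.05 (-6.55 to -1.44), Cox7c at -1.64 (-2.57 to -1.07) and Id1, a target of BMP signalling, at -1.60 (-2.83 to -0.95). Junos, Slc16a9, Gzmk, Emp1 and Zbtb16 were between -1.58 and -1.49. Adamtsl1 reached 9.11 in unnamed cluster 13 and Hs6st3 5.50 in intercalated cell-like cluster 14.

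The KLF family had 1 of 7 genes above 0 (median -0.34, percentile 1.42), with Klf9 at -0.90 and Klf6 at -0.57 against Klf2 at 0.20. Interferon genes had 3 of 9 above 0 (median -0.30, percentile 1.00), with Rsad2, the antiviral protein viperin, at -1.28 against Stat2 at 0.72. Procoagulant genes had 5 of 5 above 0 (median 0.42, percentile 93.4), with Vwf at 1.57. Outside these, Vegfa was at 1.35, Vcam1, a leukocyte adhesion receptor, at 1.11, Plvap at 1.10 and Nrp1 at -1.16. Proximal tubule markers, at 1 of 13 above 0 (median -0.32, percentile 0.10), and thick ascending limb markers, at 5 of 5 (median 0.62, percentile 99.9), moved with these groups. The library labelled Klf4 dEC is the denominator here and the numerator in the first comparison. A gene apart in that library alone is thus far from 0 in both comparisons, with opposite signs. Pcdh9, Cox7c and Gzmk were far from 0 in both with opposite signs. The medians of the KLF family and of thick ascending limb markers also had opposite signs in the 2 comparisons. Nos3 was at 1.07 where its label says it was lost. Counting error alone took a mean of 28.2 genes past the limit. With the larger pseudocount 24 passed in place of 223, and rescaling, which shifts this comparison by -0.14, turned the split to 91 higher and 120 lower.

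Against the control, the library labelled Klf4 dEC Nos3 null carries both labels together. It had 124 genes higher and 78 lower in endothelial cell-like nuclei, of 4586. Higher were Apold1, an immediate early gene of endothelium, at 0.938 against 0.0975 (log2 ratio 2.39, 1.92 to 5.36), Litaf, an endosomal protein induced by lipopolysaccharide, at 2.00 against 0.302 (2.39, 1.88 to 3.65), Hs3st4 at 2.09 (1.56 to 6.74), Ccdc3 at 1.92 (1.37 to 3.44) and the neurexin Nrxn3 at 4.96 against 1.59 (1.59, 1.24 to 2.05). Ndufaf7, Hs6st3, Cnot3, Smarca5 and Sdk1 lay between 1.62 and 1.83. Lower were Zbtb16 at 2.01 against 14.5 (-2.79, -3.21 to -2.51), Gpc6 at -2.77 (-4.47 to -2.18), Epha6 at -2.67 (-7.11 to -2.06), Reln at -2.54 (-4.89 to -1.90), Dgkb at -2.52 (-5.83 to -1.85) and Adh1 at -2.10 (-6.60 to -1.49). Junos, Plce1, the retinoic acid hydroxylase Cyp26b1 and the proximal tubule lactate transporter Slc5a12 lay between -1.88 and -1.75. Gpc6, Reln, Dgkb and Adh1 were also among the 10 lowest of Klf4 dEC over control, a comparison that shares the control library. In the library labelled Nos3 null, Gpc6, Reln, Dgkb and Adh1 were at 0.451, 0.195, 0.148 and 0.447. All were thus highest in the control, though Adh1 was near its control level of 0.588. Nrxn3 reached 45.7 in thick ascending limb-like cluster 19, and Plce1 reached 19.6 in podocyte-like cluster 15.

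Leukocyte adhesion genes lay above 0 in 7 of 8 (median 0.58, percentile 99.8). Relb, an NF-κB subunit, was at 1.09, Vcam1 at 1.05, Rela at 0.80 and Nfkbia, an NF-κB inhibitor, at -0.15. Unfolded protein response genes lay below 0 in 5 of 5 (median -0.51, percentile 0.66), with Herpud1 at -0.86 and Xbp1 at -0.65. Outside these lists' ends, Vwf was at 1.11, Egln3, an oxygen-sensing hydroxylase, at 1.33, the integrin Itga8 at 1.41 and Thbd at -1.05. Immediate early and heat shock genes had a median of 0.40 (percentile 79.6). Proximal tubule markers were above 0 in 1 of 14 (median -0.40, percentile 0.01), and mitochondrially encoded transcripts had a median of -0.18. A mean of 30.1 genes passed the limit by counting error alone. The larger pseudocount left 28 in place of 202, and rescaling turned the split to 76 higher and 95 lower.

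The interaction sets the Klf4 log2 ratio of the libraries labelled Nos3 null against that of the others. Of 5043 genes, 624 had a difference of at least 1 and 398 of at most -1. Among the lowest were Epb41l3 at -3.68, with ratios of 0.23 and -3.46 on the wild-type and Nos3-null backgrounds, Igsf11 at -3.44, Slc22a23 at -3.30 and Cdh18 at -3.10. H2-D1 had the highest, 3.19, with ratios of -0.49 and 2.70, followed by Ckb at 3.04, Chchd10 at 2.99, Adamtsl1 at 2.91 and Abi3bp at 2.89. In 7 of these 9 genes the library labelled Nos3 null held the highest or lowest of the 4 levels. No test of any of these differences is possible with 1 library per genotype, the larger pseudocount left 367 genes, and rescaling turned the split to 384 and 570.

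The Klf4 log2 ratios on the 2 backgrounds share no library. Across 4048 genes they had a Pearson r of 0.24 and a Spearman rho of 0.21. Higher by the limit on both backgrounds were 14 genes, among them the interferon-inducible GTPase Iigp1, the ribosomal gene Rplp0 and the respiratory chain genes Ndufa6 and Uqcr10, against 3.08 from independent lists. Lower on both were 19 genes, among them the proximal tubule genes Slc5a12, Slc22a5, G6pc, Hnf4aos and Ppara, against 4.13. In opposite directions were 6, against 7.33. The Nos3 log2 ratios with Klf4 labelled intact and deleted, which also share no library, had an r of 0.05 across 3961 genes, with 13 genes higher in both (4.51 from independent lists), 15 lower in both (3.13) and 18 opposite (7.84). Higher in both were Litaf, Ccdc3 and Egln3, and lower in both were Zbtb16, Id1 and Hes1, a Notch target.

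**Figure D4:**
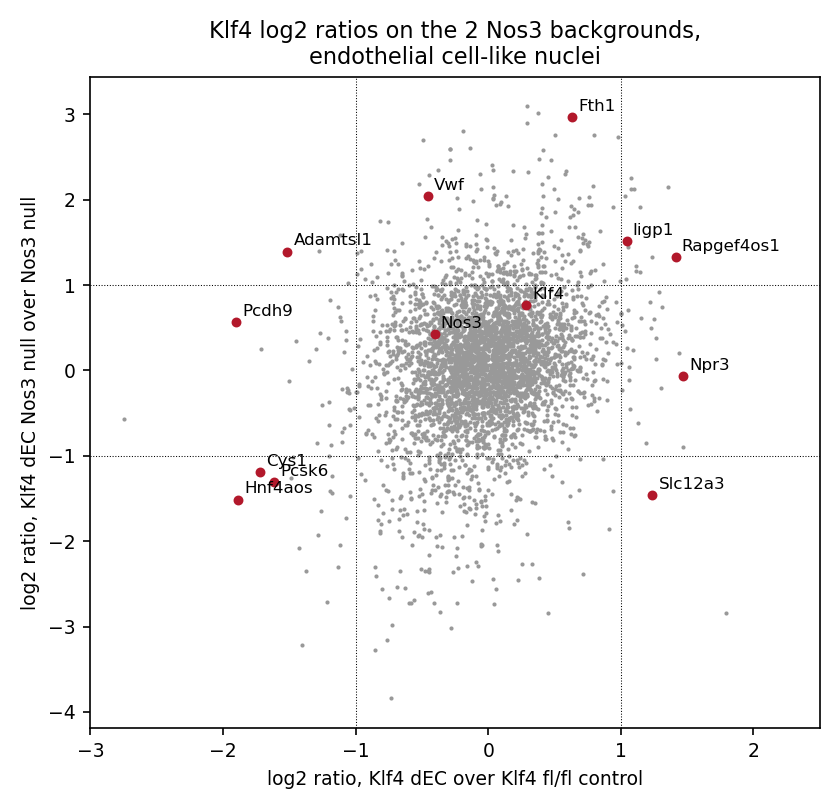
Each point is a gene in endothelial cell-like nuclei, with its log2 ratio of Klf4 dEC over control (x axis) and of Klf4 dEC Nos3 null over Nos3 null (y axis), dotted lines mark the limits of 1 and -1, and red points carry gene names. The 4048 genes have a Pearson r of 0.24, and Slc12a3 lies at 1.24 and -1.46.

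Other cell classes differed as well. In proximal tubule-like nuclei, 19 genes were higher and 9 lower in the library labelled Klf4 dEC than in the control, of 3668, with the transcriptional repressor Bcl6 at 1.12 against 3.26 (log2 ratio -1.46). Nos3 null over control gave 56 higher and 76 lower, with the sodium calcium exchanger Slc8a1 at 10.7 against 1.45 (2.81) and Fkbp5, a glucocorticoid-induced chaperone, at 0.948 against 5.85 (-2.51). Klf4 dEC Nos3 null over control gave 24 higher and 11 lower, with the clock transcription factor Npas2 at 0.916 against 0.157 (1.98) and the ectonucleotidase Nt5e at 4.42 against 1.38 (1.61).

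In podocyte-like nuclei, 55 genes were higher and 62 lower in the library labelled Klf4 dEC than in the control, of 3620, with Cox7c at 1.39 against 0.272 (2.00) and Zbtb16 at 0.686 against 3.72 (-2.28). For Klf4 dEC Nos3 null over control they were 93 and 64, with the nuclear receptor Nr4a1, an immediate early gene, at 1.93 against 0.133 (3.12) and the clock output gene Dbp at 0.0719 against 0.700 (-2.22). Over Klf4 dEC, the cell adhesion gene Opcml was at 22.5 against 2.78 (2.97). Slit diaphragm and podocyte cytoskeleton genes in this class had a median of 0.27 for Klf4 dEC Nos3 null over Nos3 null, with 12 of 15 above 0, where mitochondrially encoded transcripts had 1.48 and proximal tubule markers -0.81. In distal convoluted tubule-like nuclei, the glutamate receptor subunit Grin3a was at 0.921 in the library labelled Klf4 dEC Nos3 null against 3.43 in the control (-1.79), and Bmp6 at 0.329 against 1.12 (-1.51).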

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

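All tests in this section were chosen after the results were seen, except the test of free proximal tubule RNA, which was written down before its value was known.

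Some genes had ratios of opposite sign on the 2 backgrounds in endothelial nuclei, and none of the differences was tested. For Klf4 dEC labels, the cotransporter Slc12a3 had 1.24 with Nos3 labelled intact and -1.46 with Nos3 labelled lost (difference -2.69), and the matrix gene Adamtsl1 -1.52 and 1.39 (difference 2.91). For Nos3 null labels, with Klf4 labelled intact and then deleted, the lamin gene Lmna had 1.22 and -1.14 (difference -2.36), the receptor Adgrg6 -1.59 and 1.05 (difference 2.64) and the adrenomedullin co-receptor Ramp2 -1.46 and 1.28 (difference 2.74). Ror1 had 1.46 and -1.27 (difference -2.74), Slc22a23 1.98 and -1.32 (difference -3.30), Cdh18 1.05 and -2.05 (difference -3.10), Slc16a9 1.00 and -1.52 (difference -2.53) and Nrxn3 had opposite signs with 1.17 where Klf4 was labelled deleted (difference 2.18). RNA of other cells was not excluded for genes far lower in endothelial nuclei than elsewhere: Slc12a3 had a mean of 4.73 against 192 in distal convoluted tubule-like cluster 9, Nrxn3 2.36 against 45.7 in cluster 19, Slc16a9 0.829 against 8.41 in cluster 1, Slc22a23 1.18 against 9.86 in cluster 3, Ror1 1.16 against 8.55 in cluster 18 and Adamtsl1 1.23 against 9.11 in cluster 13.

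The library labelled Nos3 null had lower mitochondrially encoded transcripts than the control in 20 of the 20 clusters tested, the first 20 of 23. Ribosomal protein genes, whose RNA lies mostly outside the nucleus, were below the control in 20 of these 20 as well (median -0.49, range -1.25 to -0.18). This is the direction that a loss of cytoplasmic RNA before or during nuclei preparation predicts. In the library labelled Klf4 dEC Nos3 null these genes were above the control in 20 of 20 clusters (median 0.31). A shift of ribosomal protein genes shared by these clusters is thus not particular to 1 library, but its direction was opposite. Mitochondrially encoded transcripts in Klf4 dEC Nos3 null were below the control in 9 clusters and above in 11 (median 0.03). A fall of both groups in 20 of 20 clusters was seen only in the library labelled Nos3 null. Free proximal tubule RNA was left open: as a share of the proximal tubule level, 10 of 14 markers were higher in its endothelial nuclei than in the control's (median share 48.5% against 18.7%), but Kap was lower, at 81.0% against 193%. As a source of the differences across most genes, a Nos3 effect that does not depend on Klf4 was argued against by an r of 0.0513 between the Nos3 ratios on the 2 Klf4 backgrounds, while for few genes it stays open, with 13 higher and 15 lower in both against 4.51 and 3.13 from independent lists, and 18 opposite against 7.84. An effect of Nos3 loss only where Klf4 is intact stays open, because there is 1 library of this genotype.

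Clock genes differed between the library labelled Klf4 dEC Nos3 null and the control in many of the first 20 clusters, with the activators Npas2 and Arntl higher (medians 1.43 and 1.23) and Dbp, Tef, Per2 and Ciart lower (medians -1.13, -0.80, -0.70 and -0.94). The library labelled Nos3 null differed from the control in these directions too, with Arntl higher in 18 clusters (median 0.79), Dbp lower in 18 (-0.73) and Ciart lower in 17 (-0.82). Over the 19 other clusters the 95% interval of the median left out 0 for all 6 genes, by 0.32 or more. The genes were picked because they differed across clusters, and these clusters come from the same libraries. The interval thus describes differences of these 6 genes outside endothelial nuclei, and is no test of an effect confined to endothelial nuclei. Arntl in endothelial nuclei was at -0.04 (-0.71 to 0.66). Because of the same choice of genes, their shared directions in 110 of 114 gene and cluster pairs weigh nothing for or against kidneys collected at different phases of the daily cycle. Other clock genes were mixed, with Per1 higher in 7 and lower in 13 clusters, Cry1 in 11 and 9, Clock in 12 and 8 and Bhlhe41 in 3 and 12, and Cry2 was lower in 18. Collection hours are not given in the sources used here and each genotype has 1 library, so the cause stays open.

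Klf4 and Nos3 were not lower where the labels say they were deleted. Free RNA spread over all droplets was argued against as the source of the Klf4 counts: in both libraries labelled with Klf4 deletion, endothelial nuclei held at least 14.03 times the Klf4 UMIs per nucleus of proximal tubule-like ones, 0.125 (0.0858 to 0.171) against 0.00635 (0.00395 to 0.00974) in Klf4 dEC and 0.167 (0.113 to 0.237) against 0.0119 (0.00783 to 0.0176) in Klf4 dEC Nos3 null, while urothelium-like nuclei held 0.151 and 0.113. Removal of the counted Klf4 RNA from nearly all endothelial nuclei was argued against by counting intervals of the log2 ratio that reach down only to -0.43. An exchange of the control and Klf4 dEC labels could not be excluded, with a ratio of 0.29 (-0.43 to 1.10), and other exchanges were not tested. Klf4 was lowest, 0.445, in the library labelled Nos3 null and Nos3 lowest, 0.930, in the one labelled Klf4 dEC. The log2 ratios to the control were -0.40 for both, with intervals that include 0 (-1.37 to 0.42 and -1.07 to 0.14). Endothelial markers as a group were also below the control in the library labelled Nos3 null. A deletion that spares the counted 3' end, or one present in few nuclei, was not tested, nor were droplets with 2 nuclei.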

How the results depend on the processing

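Of 55 values under other settings, 27 stayed within 1.5 times the first value, 28 moved further and 0 reversed. Of 100 log2 ratios of named genes, 70 left their counting interval with the larger pseudocount, 45 after the median of the other clusters was subtracted, 1 with rescaling and 0 with the smaller pseudocount, and 0 reversed. Counts are given in the order Klf4 dEC over control, Nos3 null over control, Klf4 dEC Nos3 null over Nos3 null, over Klf4 dEC and over control, and interaction. The first counts were 148, 618, 846, 223, 202 and 1022. A pseudocount of 0.5 per 10000 gave 16, 229, 366, 24, 28 and 367, since it shrinks the ratios of low genes. A pseudocount of 0.01 gave 228 for the first comparison, 348 for the fourth and 332 for the fifth. Without a filter there were 508, 1319, 1824, 724, 716 and 2598, as more genes entered, and with a filter of 2 per 10000 there were 19, 208, 254, 27, 30 and 255, as fewer did. A limit of 0.6 gave 682, 1471, 1790, 875, 833 and 2106, since it is smaller. Subtracting the median of the other clusters, a setting chosen after the data were seen, moved only the count of Nos3 null over control, to 387. It turned the split of that comparison from 332 higher and 286 lower to 126 and 261. The split of Klf4 dEC over control went from 64 and 84 to 33 and 68. That of Klf4 dEC Nos3 null over Nos3 null went from 433 and 413 to 333 and 236. Leaving out genes low against another cluster, also chosen afterwards, moved no count. Median-ratio rescaling moved no count but shifted log2 ratios by 0.05, 0.08, -0.17, -0.14 and -0.09 in the same order of comparisons. It turned the splits to 292 higher and 513 lower, 91 and 120, and 76 and 95 in the last 3 comparisons, and to 384 and 570 for the interaction. The correlation of the Klf4 ratios was 0.24 at first and 0.17 to 0.32 elsewhere. Of 83 gene list medians, 20 lay in the outer 2.5% at either end, against 19 with 5 bins and 21 with the larger pseudocount. Where the construction does not show it, the cause was not tested. The alternative for cell class shares was not run, because it needs single nuclei. No paired analysis was possible because there is 1 library per genotype, and the shared replicate number 1 pairs nothing.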

Other observations

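Outside the endothelium, the library labelled Klf4 dEC differed from the control by large ratios in principal cell-like nuclei of the collecting duct. Slco4a1, an organic anion transporter, was at 4.62 against 0.316 (log2 ratio 3.50), Ranbp3l at 43.6 against 4.30 (3.31) and Akr1b3, the aldose reductase that makes the osmolyte sorbitol, at 3.64 against 0.339 (3.09). Ranbp3l was also higher in thick ascending limb-like nuclei, at 32.3 against 4.78 (2.73), and was among the 3 highest genes in 4 classes. Akr1b3 was at 13.8 against 1.16 in thin limb-like nuclei (3.47). In the library labelled Klf4 dEC Nos3 null, Slco4a1 and Akr1b3 were at 0.314 and 0.450 in principal cell-like nuclei, near the control. Akr1b3 is most active in the inner kidney, and the depth to which each piece was dissected is not given in the sources used here.

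Zbtb16, induced by glucocorticoids, was among the 3 lowest genes of 5 classes in the library labelled Klf4 dEC Nos3 null against the control, between -3.34 and -1.40. Its mean over 20 clusters was 4.31 in the control against 1.90, 1.33 and 1.10 in Klf4 dEC, Nos3 null and Klf4 dEC Nos3 null. Fkbp5, another glucocorticoid target, had means of 5.03, 2.81, 1.38 and 2.16. These differences were not confined to endothelial nuclei, and their cause was not tested.

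In epithelial classes, antioxidant genes in the library labelled Klf4 dEC over control had a median of 0.24 in proximal tubule-like nuclei (9 of 12 genes above 0, percentile 99.9), 0.36 in thick ascending limb-like (10 of 12, percentile 100) and 0.43 in podocyte-like ones (9 of 10, percentile 99.9). Mitochondrially encoded transcripts moved the same way, with 0.19 (percentile 99.2), 0.26 (99.5) and 0.15 (96.0) in these classes, though -0.12 and -0.06 in proximal tubule-like clusters 6 and 12. In Klf4 dEC Nos3 null over control, antioxidant genes had 0.44 in proximal tubule-like nuclei (9 of 12, percentile 100), the unfolded protein response -0.57 (2 of 6, percentile 0), immediate early and heat shock genes 0.68 (5 of 5, percentile 100) and mitochondrially encoded transcripts 0.20 (8 of 10, percentile 98.6). Clock genes had -0.71 in podocyte-like nuclei of that comparison (3 of 9, percentile 0), where proximal tubule markers had -0.45 (0 of 13, percentile 0).

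Shares of nuclei rest on the inferred nuclei numbers and were not made as planned. In the order control, Klf4 dEC, Nos3 null and Klf4 dEC Nos3 null, endothelial cell-like nuclei were 3.99% (3.54 to 4.48), 4.13% (3.67 to 4.62), 4.67% (4.19 to 5.19) and 3.39% (2.92 to 3.90). Proximal tubule-like nuclei were 46.0%, 47.9%, 51.1% and 39.5%, and thick ascending limb-like nuclei 21.4%, 15.3%, 14.98% and 24.9%. The unnamed clusters 7, 13 and 17, kept out of classes by limits set after the table was seen, held 4.20%, 5.39%, 4.34% and 5.96%, then 2.36%, 2.92%, 3.34% and 1.53%, then 1.61%, 1.87%, 2.33% and 1.27%. Intervals are exact binomial ones and cover counting error only. The piece of cortex taken and the depth gap, 2534 median UMIs in Nos3 null against 4840 in the control, bear on such shares.

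A follow-up is to count reads over each exon of Klf4 and Nos3 in endothelial nuclei. Klf4 stood there at 0.779 in the library labelled Klf4 dEC against 0.621 in the control. Such a count can decide only where the 3' tags cover the removed exons in the control, which was not checked. Reads missing over the removed exons in the labelled libraries alone would show the deletion, and even cover would count against the labels. Further libraries per genotype, collected at a fixed hour and dissected to the same depth, would test the clock, glucocorticoid target and Nos3 null differences.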
